A study of Mus musculus with 2 samples.

How the data were processed

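Small RNA of embryonic day 16.5 mouse lung was sequenced in 2 libraries, labelled biological replicates 1 and 2 of one tissue. The values used are counts of reads per microRNA gene, as the authors deposited them, with no normalization. Per the file headers the tables refer to assembly mm10 and GENCODE annotation release M4 and derive from aligned reads. The aligner, the counting program, their versions and any adapter trimming are not given in the sources used here. Each table holds 3 count columns and 4 summary lines for reads that are unmapped, match several loci, lie outside genes or are ambiguous. By their values, the first count column is the sum of the other columns in all 1973 genes, so it ignores strand, and the other columns hold the sense and the opposite strand. The column without strand was used throughout, because no column is named for use. The summary lines stayed out of totals and tests. Reads that match several loci have their own line, so genes with near-identical copies may be counted too low, and a gene and its opposite-strand partner cannot be told apart in the column used.

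CPM was computed by scaling the counts over microRNA genes to a total of 1e+06 in each library. Gene symbols, coordinates (1-based) and host genes come from GENCODE release M21 on the same mm10 build, matched by identifier without version, and 1894 of 1973 identifiers matched. Genes were called sequence copies where their hairpin transcripts share 22 bases with another microRNA gene. A gene was called detected with at least 10 counts in each library. The depth was 6376715 and 4123748 gene counts, and a count of 0 is taken to allow up to 3 counts. Intervals are exact Clopper-Pearson intervals at 95%, converted to folds. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

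The libraries were compared with a two-sided exact conditional binomial test per detected gene against the library totals, with Benjamini-Hochberg adjustment and a threshold of 0.05. Such p-values compare the reads of these libraries and say nothing of conditions. They weigh a difference against counting error alone and hold no estimate of the spread between libraries. Agreement was measured by Pearson's and Spearman's correlation of log2(CPM + 1) and by the common dispersion of edgeR 4.0.16 with TMM factors and an intercept-only design, with 200 resamples of genes. DESeq2 1.42.0 gave alternative size factors. Analyses ran in R 4.3.3 and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. The median level of each of 21 gene lists was set against 10000 random lists, and its median log2 ratio against 10000 lists whose members came from genes up to 10 ranks away in mean level. Neighbouring genes on one strand within 10 kb were compared by a one-sided permutation test with 100000 resamples.

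The groups, the gene lists, the tests, most alternatives and the rule for named genes were fixed before the data were examined. The rule takes the 15 genes with the highest mean CPM, the 5 genes higher in each replicate with the largest fold among those past the binomial test at a mean of 100 CPM or more, and the most abundant detected members of each list. Alternatives covered the count minimum, the count column, the scaling, the pseudocount, the distance between neighbours, the most abundant gene and each replicate left out. Strand-resolved counts, thinning of the deeper library and a random split of the reads into 2 parts were added after seeing the data. Left out were a test of conditions, which a single group does not allow, and signal tracks and alignments, which were not used here.

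The steps were tested on simulated counts drawn from the real means and depths over 351 genes. The binomial test found 76.0% of genes changed by 1.25-fold, 77.6% at 1.5-fold and 100% at 2- and 4-fold, and called 0% of unchanged genes. The counts for that test held counting noise only, with no spread between libraries. They were scaled by the totals of the unchanged genes and not by the library totals. These rates therefore do not carry over to the real libraries. A simulated biological coefficient of variation of 20% was estimated as 18.6% over 346 genes.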

Results

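MicroRNA levels were measured by sequencing the small RNA fraction (under 30 bases, per the labels) of lungs from mouse embryos at embryonic day 16.5 of the B6NCrl strain. At this age the branching airway tree is lined by epithelium and surrounded by mesenchyme and vessels. The libraries form a single group of 2 biological replicates, each made from lungs of male and female embryos pooled together. The pool of replicate 2 came from 41 embryos, and the number for replicate 1 was not given in the sources used here. The table of replicate 1 accounted for 12868638 reads and that of replicate 2 for 8452506. Of these, 6376715 and 4123748 were counted to microRNA genes, which is 49.6% and 48.8% (mean 49.2% ± 0.541, SD, n = 2). Reads that matched several loci made up 30.0% and 31.8%, unmapped reads 17.98% and 16.6%, and mapped reads outside microRNA genes 2.49% and 2.84%. At these depths a count of 0 allows up to 0.470 CPM (counts scaled to a gene total of 1e+06) in replicate 1 and 0.727 CPM in replicate 2. The labels name no other condition, so the comparisons below are among microRNA genes and between the 2 libraries.

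The first question was which microRNAs the lung contained and at what level. Mir322 had the highest mean, 84676 CPM ± 2070 (SD, n = 2), and Mir126a, a microRNA of endothelial cells, was at 83199 ± 5768. Their order differed between the libraries, since in replicate 1 Mir126a (87277 CPM) lay above Mir322 (83213 CPM). Mir143, which is abundant in smooth muscle and other mesenchymal cells, reached 71247 ± 1447. The let-7 genes Mirlet7g and Mirlet7i, members of a family that accumulates as tissues differentiate, were at 62701 ± 2333 and 59383 ± 6815. Mir335, which lies in an intron of the imprinted gene Mest, was at 50501 ± 1627.

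Mir322 (ENSMUSG00000065418.1) lies on chromosome X at 53054255 to 53054349, minus strand, within no other annotated gene (mm10). Mir126a (ENSMUSG00000065540.1) lies on chromosome 2 at 26591357 to 26591429, plus strand, in Egfl7, where it overlaps an annotated exon. Mir143 (ENSMUSG00000065445.2) lies on chromosome 18 at 61649196 to 61649258, minus strand. Mirlet7g (ENSMUSG00000065440.1) is in an intron of Wdr82 on chromosome 9 at 106178840 to 106178927, and Mirlet7i (ENSMUSG00000065406.2) overlaps an exon of D630033A02Rik on chromosome 10 at 122985640 to 122985724. Mir335 (ENSMUSG00000065501.1) is on chromosome 6 at 30741299 to 30741396.

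The next genes in order of their means were Mir99a (35435 CPM ± 2391, chromosome 16 at 77598936 to 77599000, in an intron of Mir99ahg), Mir26b (31561 ± 382, chromosome 1 at 74394310 to 74394394, in an intron of Ctdsp1) and Mir23b (26797 ± 1333, chromosome 13 at 63300484 to 63300557). Mir130a (25740 ± 932, chromosome 2 at 84741115 to 84741178) and Mir10a (23048 ± 851, chromosome 11 at 96317165 to 96317274) followed. Mirlet7d (19889 ± 86.8, chromosome 13 at 48536012 to 48536114), Mir17 (18856 ± 1119, chromosome 14 at 115043671 to 115043754, overlapping an exon of Mir17hg) and Mir30e (17272 ± 929, chromosome 4 at 120772606 to 120772697, in an intron of Nfyc) were next. Mir449a, a microRNA of multiciliated cells, was the last of the 15 at 16513 ± 2732 (chromosome 13 at 113037534 to 113037624, in an intron of Cdc20b). All of these values are means ± SD with n = 2. Genes with sequence copies may be counted too low, so this order is that of the counted reads. The order by library differed from that of the means for Mir23b and Mir130a in replicate 1, and for Mir449a, which lay above Mir17 and Mir30e in replicate 2.

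**Figure D1:**
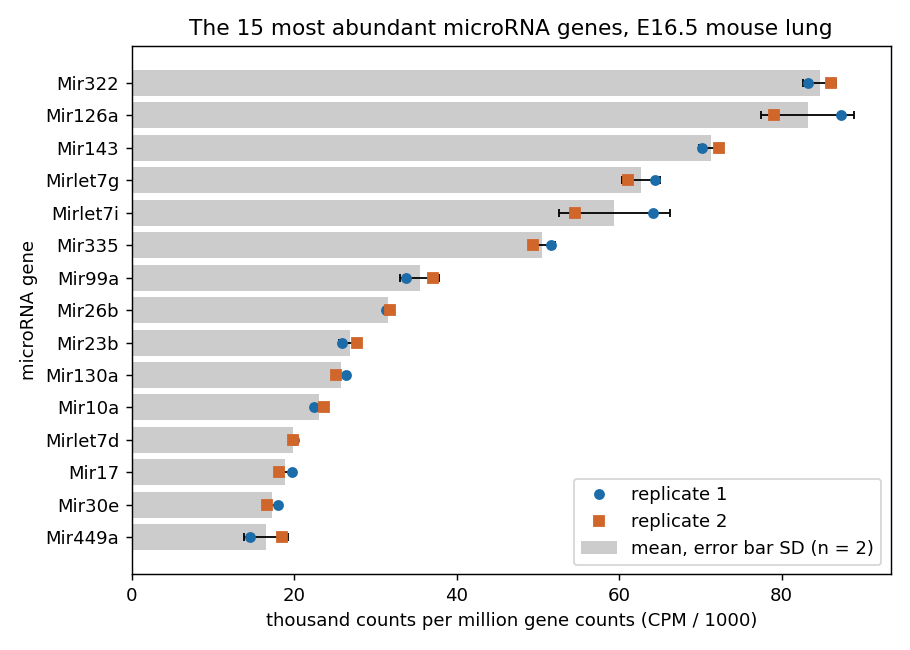
Level of the 15 most abundant microRNA genes in embryonic day 16.5 lung, as CPM / 1000 (horizontal axis, from 0). Grey bars are means, error bars SD (n = 2), circles replicate 1 and squares replicate 2; Mir322 has the highest mean, 84676 CPM, while Mir126a is higher in replicate 1.

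Of 1973 microRNA genes in the tables, 347 (17.6%) had at least 10 counts in each library and are called detected here. A further group of 1264 genes had 0 counts in both libraries. Among the 1894 genes with a hairpin sequence, 871 share 22 bases with another microRNA gene, and 62 of these were detected. Low or 0 counts of such genes may reflect the counting and do not show that they are silent. Mir322 alone held 8.47% ± 0.207 of gene counts (SD, n = 2). The 10 most abundant genes of each library held 53.1% ± 0.985 and the 50 most abundant 86.5% ± 0.514. There were 22 genes at 10000 CPM or more, 99 at 1000 CPM or more and 194 detected genes at 100 CPM or more.

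Gene families of general growth and differentiation took large shares of the counts. The let-7 family (10 of 10 measured members detected) held 16.3% ± 1.01 of gene counts, led by Mirlet7g, Mirlet7i and Mirlet7d. The miR-15/16 family (8 of 9 detected) held 9.87% ± 0.222, most of it Mir322, with Mir15a at 4276 CPM ± 519. The miR-17~92 clusters and their paralogues, which promote proliferation of embryonic lung progenitors, had 15 of 15 members detected and held 4.57% ± 0.231, led by Mir17, Mir93 (7158 ± 174) and Mir20a (6808 ± 901). The miR-30 family (6 of 6 detected) held 3.70% ± 0.0833, led by Mir30e and Mir30a (12764 ± 250), and the miR-26 family (3 of 3 detected) held 3.16% ± 0.0379, nearly all of it Mir26b. Other microRNAs studied in lung (14 of 14 detected) held 4.97% ± 0.0569, led by Mir130a and Mir21a (8695 ± 69.2).

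Lists of microRNAs typical of the cell types of the lung covered both epithelium and stroma. Endothelial markers (11 of 11 detected) held 16.2% ± 0.0598, led by Mir126a, Mir99a and Mir10a. Mir126a held 8.32% of gene counts, Mir99a 3.54% and Mir10a, which is also counted in the Hox-embedded list, 2.30%. Which cells each microRNA came from was not measured, so the shares of these lists do not give cell proportions. Mesenchymal and smooth muscle markers (12 of 15 detected) held 8.30% ± 0.163, led by Mir143, Mir140 (4692 CPM ± 83.3) and Mir214 (4608 ± 216). Epithelial markers (10 of 10 detected) held 4.33% ± 0.162, led by Mir429 (14764 ± 461), Mir200c (10279 ± 499) and Mir200b (5608 ± 91.0), all of the miR-200 family that maintains epithelial identity. Multiciliated cell markers (5 of 5 detected) held 1.75% ± 0.294, led by Mir449a and Mir34c (941 ± 196). The neuroendocrine list (3 of 4 detected) held 0.282% ± 0.0147, nearly all of it Mir375 (2723 ± 153). Sequence shared with another microRNA gene was found in 8 of 15 mesenchymal, 3 of 11 endothelial and 2 of 4 neuroendocrine members, which may be counted too low.

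Markers of tissues other than lung and of blood were lower in the counted reads. Of the measured members, 9 of 12 neural, 3 of 8 muscle, 2 of 4 liver and 1 of 8 blood members share sequence with another microRNA gene. Such genes may be counted too low, so the low shares of these lists, above all the neural list, may partly reflect the counting. Blood and immune markers (7 of 8 detected) held 0.195% ± 0.0204, led by Mir223 of myeloid cells (719 CPM ± 30.2) and Mir451a of red cells (578 ± 240). With opposite-strand counts given to the gene annotated there, an alternative added after seeing the data, this list held 0.315%, and Mir142 of blood cells, counted under Mir142b, was above Mir223 at 1204 CPM ± 76.8. Cardiac and skeletal muscle markers (5 of 8 detected) held 0.114% ± 0.00836, led by Mir206 (469 ± 247) and Mir208a (430 ± 150). Neural markers (7 of 12 detected) held 0.0460% ± 0.00577, led by Mir132 (230 ± 11.7), and the liver list (3 of 4 detected) held 0.0455% ± 0.0339, led by Mir122 (356 ± 346) and Mir192 (63.8 ± 2.06). The liver share was 0.0216% in replicate 1 and 0.0695% in replicate 2, below and above the neural share of 0.0419% and 0.0501%, so the order of these lists rests on the library. The Mir302 cluster (3 of 5 detected) held 0.00309% ± 0.000181, led by Mir302a (14.7 ± 2.95), and the Mir290 cluster (3 of 7 detected) held 0.00117% ± 3.07e-05, led by Mir293 (4.71 ± 0.889); both clusters are typical of pluripotent cells.

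The imprinted and Hox loci were also represented. The Dlk1-Dio3 cluster of chromosome 12 (43 of 49 detected) held 5.34% ± 0.252, led by Mir411 (9457 CPM ± 366.7), Mir127 (6288 ± 388) and Mir487b (5499 ± 867). The Hox-embedded microRNAs (6 of 6 detected) held 2.45% ± 0.156, led by Mir10a and Mir10b (1258 ± 552). The Sfmbt2 cluster (8 of 26 detected) held 0.319% ± 0.000938, led by Mir467d (949 ± 21.8), and 25 of its 26 measured members share 22 bases with another microRNA gene, so their levels are uncertain. The H19-Igf2 locus (2 of 2 detected) held 0.0625% ± 0.00318, led by Mir483 (555 ± 35.0). All shares and levels of these lists are means ± SD with n = 2, and their leading genes are ordered by the mean. In replicate 1 Mir20a lay above Mir93, Mir451a above Mir223 and Mir208a above Mir206, and in replicate 2 Mir214 lay above Mir140 and the endothelial list above the let-7 list. Against random lists of all microRNA genes, the median CPM of 14 of the 21 lists lay at or above percentile 97.5. Of the 1973 genes, 1264 had 0 counts in both libraries, so a list can pass without being high among detected genes. The neural list, for one, stood at percentile 99.78 against all genes and 10.2 against detected genes. Against detected genes only, 4 lists passed: the let-7 family (99.97), epithelial markers (99.02), the miR-30 family (98.74) and the miR-15/16 family (97.79).

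**Figure D2:**
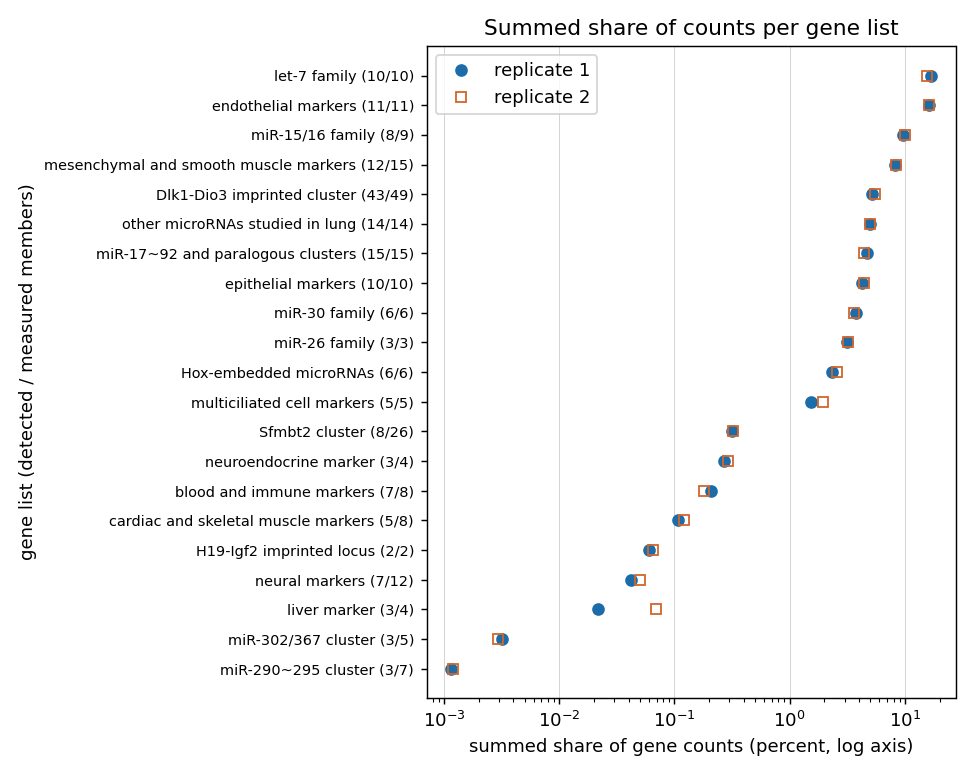
Summed share of gene counts for the 21 gene lists, in percent on a log axis, with the detected and measured members of each list in parentheses. Filled circles are replicate 1 and open squares replicate 2; the let-7 family (16.3%) and endothelial markers (16.2%) lie highest and the Mir290 cluster lowest.

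A second question was how alike the microRNAs of one genomic cluster were, since neighbours can share a primary transcript. The cluster of Mir322 on chromosome X (53047997 to 53054349) held 10.1% ± 0.119 of gene counts (SD, n = 2) over 7 detected genes, yet Mir322 was 6406-fold above Mir450-2, a gene with a sequence copy. In the Mir17 cluster of chromosome 14 (3.14% ± 0.223), Mir17 lay 2050-fold above Mir19b-1, whose sequence has a copy as well, and Mir19a had 42.9 CPM ± 8.25. Mir143 lay 66.1-fold above Mir145a (1077 CPM ± 61.0) on chromosome 18, and Mir449a lay 787-fold above Mir449b (21.0 ± 0.506) on chromosome 13. In the Mir429 cluster of chromosome 4 the highest gene, Mir429, was 14.4-fold above the lowest, Mir200a (1028 ± 68.7).

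Across all microRNA genes, the mean log2(CPM + 1) of neighbours on the same strand within 10 kb correlated with r = 0.690 over 310 pairs (one-sided permutation test, p = 1e-05, the smallest that the permutations can give). These pairs include a run of 107 genes at the Sfmbt2 locus of chromosome 2, of which only 10 were detected. Neighbours there are mostly alike in having few or 0 counts, so r partly reflects this locus. How much it contributes was not measured. Among detected genes alone r was 0.19996 over 109 pairs (one-sided permutation test, p = 0.0149). The median difference between detected neighbours was 8.60-fold, and 47.7% of these pairs differed by more than 10-fold. Some pairs hold a gene with a sequence copy, such as Mir30c-1, which lay 326-fold below Mir30e. Part of these differences may therefore reflect the counting, and pairs without such genes were not measured separately. These correlations are across genes, which are not independent replicates.

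**Figure D3:**
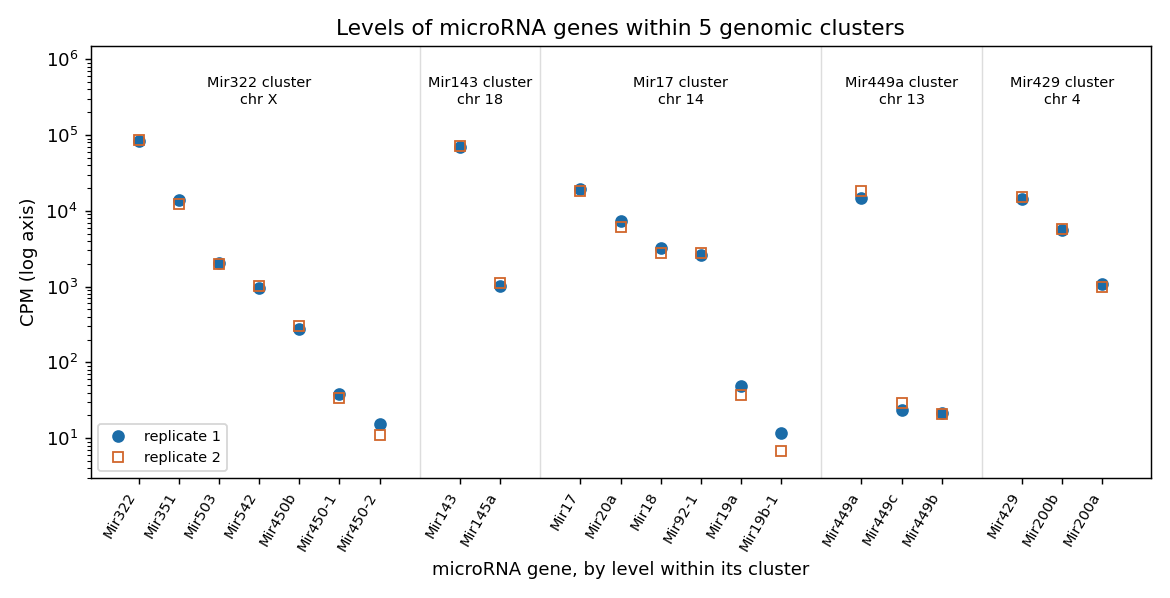
Level of each microRNA gene in 5 genomic clusters, in CPM on a log axis, ordered by level within each cluster. Filled circles are replicate 1 and open squares replicate 2; within the Mir322 cluster the levels span 6406-fold.

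The next question was how far the 2 libraries differed. With a single library per pool, differences between the pools of lungs cannot be told apart from those of library preparation. Mir122, the abundant microRNA of hepatocytes, was 5.39-fold higher in replicate 2 (95% interval 4.95 to 5.86), at 601 CPM against 111. Mir196b, which lies in the Hoxa cluster, was 5.06-fold higher (4.43 to 5.80), and Mir206, a microRNA of skeletal muscle, 2.19-fold higher (2.06 to 2.32). Mir10b of the Hoxd cluster was 1.90-fold higher (1.83 to 1.97) and Mir92b 1.36-fold higher (1.32 to 1.40). In the opposite direction, Mir451a was 1.83-fold higher in replicate 1 (1.73 to 1.94), at 747 CPM against 408, and Mir208a, a microRNA of heart muscle, was 1.65-fold higher (1.55 to 1.76).

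Mir122 lies on chromosome 18 at 65248861 to 65248926, Mir196b on chromosome 6 at 52230081 to 52230165, overlapping an exon of Hoxa9, and Mir206 on chromosome 1 at 20679010 to 20679082. Mir10b lies on chromosome 2 at 74726070 to 74726137, within introns of Hoxd3 and Hoxd4. Mir451a lies on chromosome 11 at 78073170 to 78073241 and Mir208a on chromosome 14 at 54949060 to 54949142, in an intron of Myh6. The other genes higher in replicate 1 were Mir181b-2 (1.33-fold, 1.28 to 1.39), Mir7j (1.29-fold, 1.13 to 1.46) and Mirlet7a-2 (1.28-fold, 1.17 to 1.40). Mir181b-2 and Mirlet7a-2 share sequence with other genes and are uncertain.

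Most genes were close. Across the 347 detected genes, log2(CPM + 1) of the libraries correlated with Pearson's r = 0.995 and Spearman's rho = 0.995, and 188 of the 194 genes at 100 CPM or more lay within 1.5-fold. The biological coefficient of variation was 14.7% (edgeR common dispersion, 10.1 to 18.96% when genes were resampled). It holds any spread from library preparation as well as that between the pools. The libraries differed by more than counting noise (chi-square 27486 on 346 degrees of freedom), so they are not a single library under different labels.

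By an exact binomial test of each gene's counts, 163 of the 347 detected genes (47.0%) differed between the libraries, 57 higher in replicate 1 and 106 higher in replicate 2. That split depended on the scale: it was 74 and 84 with edgeR's TMM factors, and 78 and 75 with DESeq2's size factors. Only 18 genes also differed by at least 1.5-fold, 4 higher in replicate 1 and 14 in replicate 2, and 6 of the 18 were at 100 CPM or more. With edgeR's exact test at the common dispersion the count was 5, all higher in replicate 2, but that dispersion was estimated from the same libraries and already contains their difference, so it does not sort single genes. Both tests compare these libraries and not conditions.

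**Figure D4:**
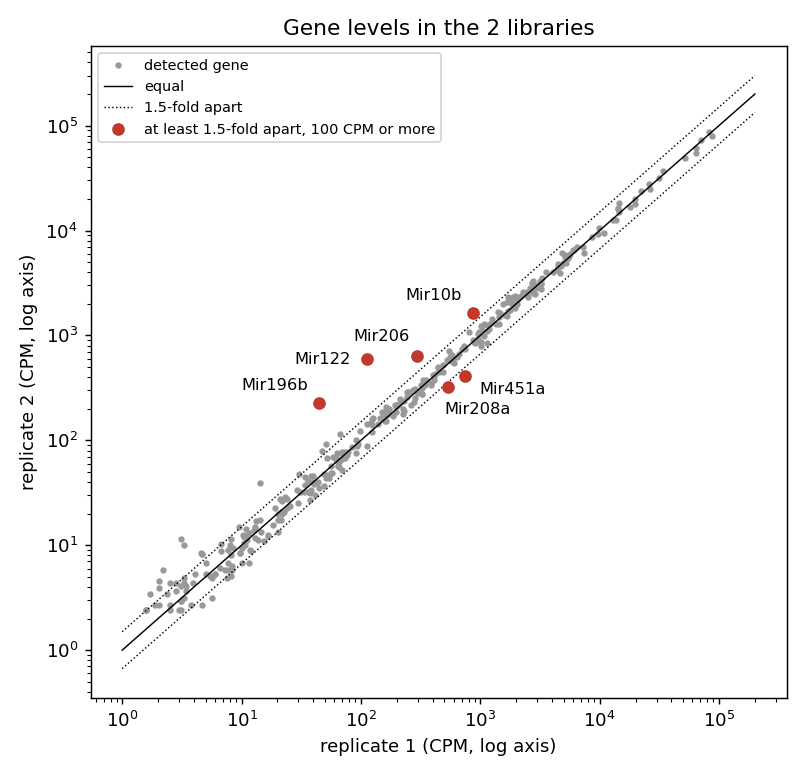
Level of each detected gene in replicate 1 (horizontal) and replicate 2 (vertical), in CPM on log axes, with lines for equal levels and for a 1.5-fold difference. Red points are the 6 genes at 100 CPM or more that differed by at least 1.5-fold, among them Mir122 (5.39-fold) and Mir196b (5.06-fold).

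In some lists the genes that differed between the libraries lay mostly on one side. In the multiciliated list, 3 of 5 detected members were higher in replicate 2 (Mir449a, Mir34c and Mir34b) and none lower, with a median log2 ratio of replicate 1 over replicate 2 of -0.34, at percentile 0.345 of 10000 random lists matched on mean expression. In the Hox-embedded list, 4 of 6 were higher in replicate 2 (Mir10a, Mir10b, Mir196b and Mir615) and none lower (median -0.47, percentile 0.360). In the Dlk1-Dio3 list, 21 of 43 were higher in replicate 2 and 2 higher in replicate 1 (median -0.12, percentile 1.63), among them Mir487b and Mir127. In the let-7 list, 6 of 10 were higher in replicate 1 and 1 higher in replicate 2 (median 0.08, percentile 97.4), and in the miR-17~92 list 7 of 15 against 3 (median 0.11, percentile 98.5). The percentiles are not corrected for the 21 lists and treat genes as independent, although members of one genomic cluster can share a transcript, and that of the let-7 list is under 97.5. The balance of calls in these 5 lists kept its direction under both other scales, at 13 against 3 and 12 against 3 for the Dlk1-Dio3 list.

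In the remaining lists, members higher in replicate 1 and in replicate 2 numbered 1 and 6 for endothelial markers, 2 and 5 for mesenchymal markers, 2 and 2 for muscle markers, 1 and 2 for neural markers, 4 and 3 for other lung microRNAs, 0 and 1 for the neuroendocrine list and 0 and 1 for the liver list. For these 7 lists the side with more calls was the same under all scales, or the sides were equal under all. It was not the same for epithelial markers (2 and 6, but 4 and 4 with DESeq2's size factors), the miR-15/16 family (2 and 5, but 3 and 3), the miR-30 family (2 and 2, but 3 and 1) and the H19-Igf2 locus (0 and 1, but 0 and 0). It flipped under both other scales for blood markers (2 and 3), the miR-26 family (0 and 1) and the Sfmbt2 cluster (0 and 1). No member of the Mir302 or Mir290 clusters passed. Adjusted over the list alone, 4 neural members passed, against 3 when adjusted over all genes, and the counts of the other lists were equal under both adjustments (7 for let-7, 10 for miR-17~92, 23 for Dlk1-Dio3, 3 for multiciliated and 4 for Hox-embedded members). In 8 of the 21 lists the summed share and the median differed in sign between the libraries, among them the liver, muscle and blood lists.

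The final question was on which strand the reads lay. Gm25301, Gm24321 and Gm25927 had almost all of their counts on the strand opposite to the gene, where the annotation places Mir378a, Mir409 and Mirlet7e. Their opposite-strand levels were 5458 CPM ± 471, 5091 ± 239 and 4960 ± 10.8 (SD, n = 2). Mir378a lies on chromosome 18 at 61397835 to 61397900, Mir409 on chromosome 12 at 109743158 to 109743236 and Mirlet7e on chromosome 17 at 17830352 to 17830444. The same held for Gm24083 (opposite Mir191), Gm25252 (Mir376a), Mir497b (Mir497), Mir299b (Mir299a), Mir142b (Mir142), Gm25750 (Mir380) and Gm24111 (Mirlet7f-1). These 10 genes held 99.7% of all opposite-strand counts, which were 2.68% ± 0.0508 of gene counts. The level of Mir497b counted in the miR-15/16 list, and that of Mir299b in the Dlk1-Dio3 list, is therefore uncertain. With these counts given to the opposite-strand genes, the shares of 3 lists moved by more than 1 SD: blood and immune markers from 0.195% to 0.315%, above the 0.282% of the neuroendocrine list, the Dlk1-Dio3 cluster from 5.34% to 6.16%, and other lung microRNAs from 4.97% to 5.09%. Mir142 belongs to both the blood list and that of other lung microRNAs.

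**Figure D5:**
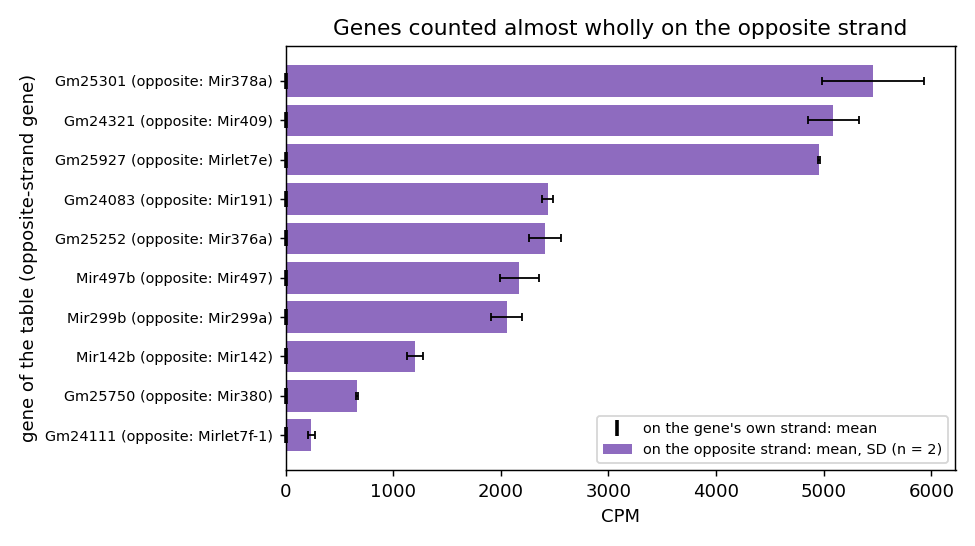
The 10 detected genes whose counts lay mostly on the strand opposite to the gene, with the gene annotated on that strand in parentheses, in CPM (horizontal axis, from 0). Bars are mean opposite-strand levels with SD (n = 2) and black ticks the mean levels on the gene's own strand; Gm25301 leads with 5458 CPM.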

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

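All tests weighed in this part were chosen after the result was seen.

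Reads that matched several loci made up 29.97% of replicate 1 and 31.75% of replicate 2, and were singled out because they are signal outside the gene counts, far above the level that a count of 0 allows. Counts on the opposite strand made up 2.64% and 2.71% of gene counts. They are part of the gene counts used in the report. They were singled out because the column that holds them alone is also far above that level. The main comparisons between libraries did not use that column, which served only as an alternative.

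For the opposite-strand counts, a general loss of strand during library preparation is argued against, since the other 337 detected genes had 0.00842% of their counts on the opposite strand when pooled. Reads of a microRNA gene annotated on the opposite strand could account for the pattern: 10 of 10 such genes have one. Mir378a, Mir409, Mirlet7e and Mir191 would then be well expressed in this lung, under the names Gm25301, Gm24321, Gm25927 and Gm24083. No biological explanation was tested.

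For the reads that matched several loci, genes with symbol numbers under 500 offer a comparison, taken without the repeated Mir297, Mir466 and Mir467 genes. The 79 genes that share 22 bases with another microRNA gene had a median of 9.20 CPM and the 223 that share none 287 CPM, a ratio of 31.3 (one-sided permutation test, p = 1e-05, the smallest that the permutations can give), which is consistent with reads of several loci being kept out of the gene counts. With the repeated genes kept the ratio was 666. Low expression of the whole family is argued against for 4 families only, which were chosen after the data were seen and hold large shares of the counts. In 4 of 4 the genes without shared bases had medians above the 180 CPM of detected genes. Other sharing genes, such as Mir124a-1, Mir9-2 and Mir133a-1, had 0 counts in both libraries. For those, low expression of the family was not examined and remains open. In the let-7 family the medians were 203 CPM for sharing and 19889 CPM for other genes, in the miR-26 family 30.2 and 31561 CPM, and in the miR-30 family 47.5 and 9763 CPM. The miR-15/16 family differed less, at 1159 and 2089 CPM, with Mir195b, which shares none, at 0.121 CPM. A true difference between copies within a family remains open and was not tested.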

How the results depend on the processing

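Some alternatives (strand-resolved counts and thinning) were chosen after the data were seen. No paired analysis was possible because the study has one group. The folds of the 10 genes named as differing kept their direction and their side of the threshold in all 70 values of the scaling, filter, sense-column and thinning alternatives. With a minimum of 1 count, 575 genes were detected, and the opposite-strand column gave 15, by its construction. The share of the 10 most abundant genes was 54.6% with the sense column, 99.7% with the opposite-strand column and 54.3% with strand-resolved counts without genes that share bases, and it ranged from 52.4 to 53.8% when a replicate was left out. Pearson's r was 0.997 with a pseudocount of 10 CPM and 0.998 in the opposite-strand column, where the biological coefficient of variation was 6.55%. The opposite-strand column gave 8 differing genes, 4 in each direction, and 0 at least 1.5-fold apart. The edgeR exact test gave 5 differing genes, 0 higher in replicate 1 and 5 in replicate 2, because it adds the spread between the libraries, and of the 10 named genes these included only Mir122, Mir196b and Mir206. Its dispersion comes from the same libraries and contains the difference, so it is no check of single genes. With random lists of detected genes only, 4 lists stood at or above percentile 97.5. Without the most abundant gene, the shares of 17 of the 21 lists moved by more than 1 SD, as did those of 7 with the sense column and 3 with strand-resolved counts. The first of these shifts follow from the smaller total: Mir322 held 8.47% of gene counts, so shares of lists without it rise, such as let-7 from 16.3% to 17.8%. The miR-15/16 family, which holds Mir322, fell to 1.54%. The sense column likewise leaves 2.68% of gene counts out of the total, and the 7 shares that moved rose. With the deeper library thinned to equal depth, 140 genes differed and 15 were at least 1.5-fold apart. With 2 libraries each list share lies within 1 SD of the mean when a replicate is left out, but the liver share of 0.0455% became 0.0695% without replicate 1 and 0.0216% without replicate 2. Depth limits genes of few counts, such as those of the Mir290 cluster. The cause of the other shifts was not tested.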

Other observations

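The tests of explanations in this part were chosen after the result was seen.

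Other clusters than those described in the report were also well represented. The pair Mir99a and Mirlet7c-1 on chromosome 16 held 3.56% ± 0.238 of gene counts (SD, n = 2), with Mir99a 224-fold above Mirlet7c-1, a gene with sequence copies. The Mir23b cluster of chromosome 13 held 2.91% ± 0.148, with Mir23b 11.7-fold above Mir27b. Mir99b and Mir125a on chromosome 17 held 1.80% ± 0.134 and lay 5.62-fold apart. The pair Mir98 and Mirlet7f-2 on chromosome X held 1.44% ± 0.108, and the Mir93 cluster of chromosome 5 held 1.30% ± 0.00566, with Mir93 16.0-fold above Mir25. In the sensory epithelial cluster of Mir182, Mir183 and Mir96 on chromosome 6 (0.676% ± 0.0158), the genes lay closer, at most 2.87-fold apart.

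The 6 genes at 100 CPM or more that differed by at least 1.5-fold are Mir122, Mir196b, Mir206, Mir10b, Mir451a and Mir208a, which as background belong to liver, the Hox loci, skeletal muscle, red cells and heart. With the reads split at random into 2 equal parts, the same 6 genes were chosen in one part. Their lowest lower 95% bound in the other part was 1.54. This split cannot decide on counting error, because these genes had already passed the binomial test and copies of one molecule can fall in both parts. A scale factor is argued against, because it moves all genes alike. All 194 detected genes at 100 CPM or more had a median log2 ratio of replicate 1 over replicate 2 of -0.0629 (robust SD 0.163). Of the 6 genes, 2 were higher in replicate 1 and 4 in replicate 2. Skeletal muscle carried over with the lung may contribute to Mir206: its neighbour Mir133b was 3.02-fold higher in replicate 2 (95% interval 1.74 to 5.38, 21 and 41 counts), while Mir1a-1, Mir133a-1 and Mir133a-2 had 0 counts and have copies. Mir144 beside Mir451a was only 1.20-fold higher in replicate 1 (95% interval 1.11 to 1.30). This argues against more red cells as the whole cause of higher Mir451a only if the 2 microRNAs keep their ratio in red cells. That ratio was not measured. Liver tissue as the source of Mir122 cannot be told apart from other sources, as Mir192 was 0.955-fold in replicate 2 over replicate 1. How much of the 65.2 and 62.3 CPM of Mir192 came from lung was not measured here. The muscle, blood and liver lists share 0 measured members with other lists. Mir142, which has no entry of its own, was placed in both the blood list and that of other lung microRNAs. Of the measured members of the muscle, blood and liver lists, 5 of 8, 7 of 8 and 3 of 4 were detected in these libraries. The design names no biological difference between the pools that could be tested.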
